A study of Mus musculus with 2 samples.

How the data were processed

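Single-cell RNA-seq had been done on synovium, the soft tissue that lines a joint, dissected from wild-type mouse knees. There were 2 libraries, 1 from control mice and 1 from mice carrying the label MMS, which the labels do not spell out. Each library pooled 20 knees. The MMS mice have the label D14, and no such number is given for the controls. Per the labels' protocols, the tissue was minced and digested with Liberase and DNase, passed through strainers, and loaded on the 10x Genomics Chromium system with the 3' v3.1 kit, which counts unique molecular identifiers (UMIs) near the 3' end of each transcript.

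Each deposited matrix holds UMI counts per gene and barcode, whole numbers that were not normalized, per the file headers and the values. The header of each matrix names Cell Ranger 5.0.0, while the submitters' processing notes name Cell Ranger 2.0.0 and the genome build mm10; the options used are not given in the sources used here. The barcode lists are the authors' own selection, and the lowest total in either was 500 UMIs. The matrices list 32285 gene identifiers, of which 32235 matched GENCODE M21 (GRCm38, the assembly that mm10 names), the source of the gene coordinates printed here. UMIs of rows that share a gene symbol were kept apart.

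All computation started from the deposited counts. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Doublets were called by scrublet (in scanpy 1.11.5) in each library separately with an expected rate of 0.06, and removed: 184 of 7075 control and 106 of 3871 MMS cells. This left 6891 of 8810 control barcodes and 3765 of 5286 MMS barcodes. Kept cells of both libraries were scaled to 10000 UMIs per cell, log-transformed and clustered together without batch integration, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9), which gave 27 clusters. The files used hold no cell annotation, so clusters were named from marker genes. The class with the highest mean marker score took the cluster where the score was at least 1.5 and led the next class by at least 0.3, with at least 3 markers detected; clusters of low depth without an own marker among their top genes were barred. These naming thresholds were set after the clusters had been seen. They left 1 cluster unnamed, led by cell-cycle genes, with 17 control and 97 MMS cells. Fibroblast-like cells were clustered again by themselves and sub-clusters called lining-like or sublining-like from markers. No cluster in the classes compared here had more markers of another class than of its own among its top 10 genes by fold against cells outside the class. Against all other cells, cluster 7 of the fibroblast-like cells had the tendon marker Tnmd there and no fibroblast marker, so results were also computed without it. Cluster 0 of the endothelial-like cells had 1 osteoblast marker there and no endothelial marker, and was kept. The choice to compare with cells outside the class was also made after the clusters had been seen.

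UMIs were summed per class and library and expressed as counts per 1000000 UMIs of the class total (CPM), without any model or test. Ratios are MMS over control with exact conditional binomial 95% intervals, and shares have exact Clopper-Pearson 95% intervals; both cover counting error only. A gene with 0 UMIs in a library took 3 counts, which makes its ratio a bound, and a share of 0 has 3 counts of the total as its limit. For a gene list, the median log2 ratio was taken over members with at least 10 UMIs over both libraries and placed among the medians of 10000 random lists of the same size matched on mean expression; the percentile describes these libraries and is not a test. Shares of cells with cell-cycle UMIs were compared after every cell had been thinned to 2000 UMIs. Fibroblast-like cells of the same depth were compared in bins of 0.5 in log2 UMIs with at least 20 cells of each library, weighted by the smaller number of cells.

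The genes named for each class followed a rule of size. Eligible genes had at least 50 UMIs in the library where they were higher, were detected in at least 5% of the class's cells there, and had a class level there of at least 0.5 times the level over all kept cells. Mitochondrial, ribosomal protein, haemoglobin, unnamed-model and sex-linked genes were left out. The 12 highest and 12 lowest ratios were named in fibroblast-like, the 8 and 8 in macrophage or monocyte-like, and the 6 and 6 in endothelial-like cells; 1 of these genes is not reported here. List members given as examples, and any other gene, were chosen after their values were seen. The markers, the 26 gene lists, this rule, the filters and the first set of alternatives were fixed before the data were examined. The other alternatives, and the lists of precursor genes, were added afterwards.

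The ratio and list calculations were tested on simulated UMI sums with 200 changed genes of known fold. The sums were Poisson draws without any spread between cells. That is the model the intervals assume, so the test checks the calculation and not the coverage in real cells. Intervals covered the true fold for 95.6% of 12420 genes at fibroblast-like depth, 95.7% of 9710 genes at macrophage or monocyte-like depth and 95.9% of 9354 genes at endothelial-like depth. The direction was recovered for 100% of the changed genes in each of these. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9. Alternatives varied the mitochondrial, UMI and doublet filters, the cluster resolution and seed, the scaling, the weight of cells and clusters, thinning, and which clusters made up a class.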

Results

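The synovium of control mice and of mice labelled MMS was profiled by single-cell RNA-seq, with 1 pooled library per group. The control library held 84900876 UMIs over 8810 barcodes and the MMS library 85597195 UMIs over 5286 barcodes. After filtering, 6891 control and 3765 MMS cells remained, with a median of 10990 and 17444 UMIs and 3257 and 4234 genes per cell. At an equal depth of 2000 UMIs, the median was 1061 genes in control and 1068 in MMS cells. The median mitochondrial share was 3.42% in control and 3.88% in MMS. There were no replicate libraries, so each difference below is between these libraries, and its interval covers counting error only. The labels give goblet cells as the cell type, but no kept cell had UMIs of 2 or more of the 8 goblet markers, 0 of 6891 in control and 0 of 3765 in MMS (limits of 3 counts in the total, 0.0435% and 0.0797%).

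The first comparison asked which cells each synovium held. Neutrophil-like cells were 0.290% (0.177 to 0.448) of control cells and 8.21% (7.35 to 9.13) of MMS cells, 20 of 6891 against 309 of 3765. Tenocyte-like cells, named from tendon markers, were 0 of 6891 in control (a limit of 3 counts, 0.0435%) and 7.62% (6.80 to 8.52) in MMS. Their cluster had 2 tendon markers and 1 chondrocyte marker among its top 10 genes. The tendon marker Tnmd was seen in 31.7% of them (152 CPM, median depth 31363 UMIs). It was also seen in 23.7% of control fibroblast-like cells (89.3 CPM, median depth 13747 UMIs). The name therefore does not mean that Tnmd was absent from control. Mural-like cells, named from markers of the smooth muscle and pericytes of vessels, were 2.19% (1.86 to 2.57) in control and 4.86% (4.20 to 5.60) in MMS. Those of MMS held the fibroblast genes Prg4 at 22766 and Fn1 at 9139 CPM, against 177 for each in MMS endothelial-like cells. Fibroblast content was therefore not separated from the mural-like share. Endothelial-like cells were 28.4% (27.3 to 29.4) in control and 18.7% (17.4 to 20.0) in MMS, and dendritic-like cells were 2.89% (2.51 to 3.31) and 0.797% (0.538 to 1.14). Of the other clusterings, only that at resolution 2.0 had a cluster that took the dendritic-like name.

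Fibroblast-like cells made up 46.7% (45.5 to 47.9) of control and 38.5% (37.0 to 40.1) of MMS cells, and macrophage or monocyte-like cells 17.6% (16.7 to 18.5) and 14.95% (13.8 to 16.1). Among non-haematopoietic cells, fibroblast-like cells were 59.8% (58.5 to 61.1) in control and 51.5% (49.7 to 53.4) in MMS. That difference of -8.28 points turned to 1.91 when tenocyte-like cells were counted with fibroblast-like cells, an alternative added after the data were seen, and to 2.26 at cluster resolution 0.5. Over all kept cells, the fibroblast-like difference of -8.14 points lay at -0.131 at that resolution. The macrophage or monocyte-like difference of -2.65 points lay at -7.90 with a mitochondrial limit of 5%, and the endothelial-like difference of -9.68 at -6.26 with a minimum of 2000 UMIs. Smaller classes were adipocyte-like (0.450% in control, 1.70% in MMS), Schwann or glial-like (0.131% and 0.823%), T or NK-like (0.972% and 0.717%) and B or plasma-like cells (0.189% and 0.531%), while unnamed cells were 0.247% and 2.58%. The tenocyte-like cluster came from the MMS library alone and may not be a type of its own. Of the 20 control cells in the neutrophil-like class, 12 lay in cluster 22, where they held no UMIs of the granule genes Elane, Mpo and Ltf and had Prtn3 at 70.9 CPM. UMI depth differed between the libraries and can set which cells pass the filters.

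**Figure D1:**
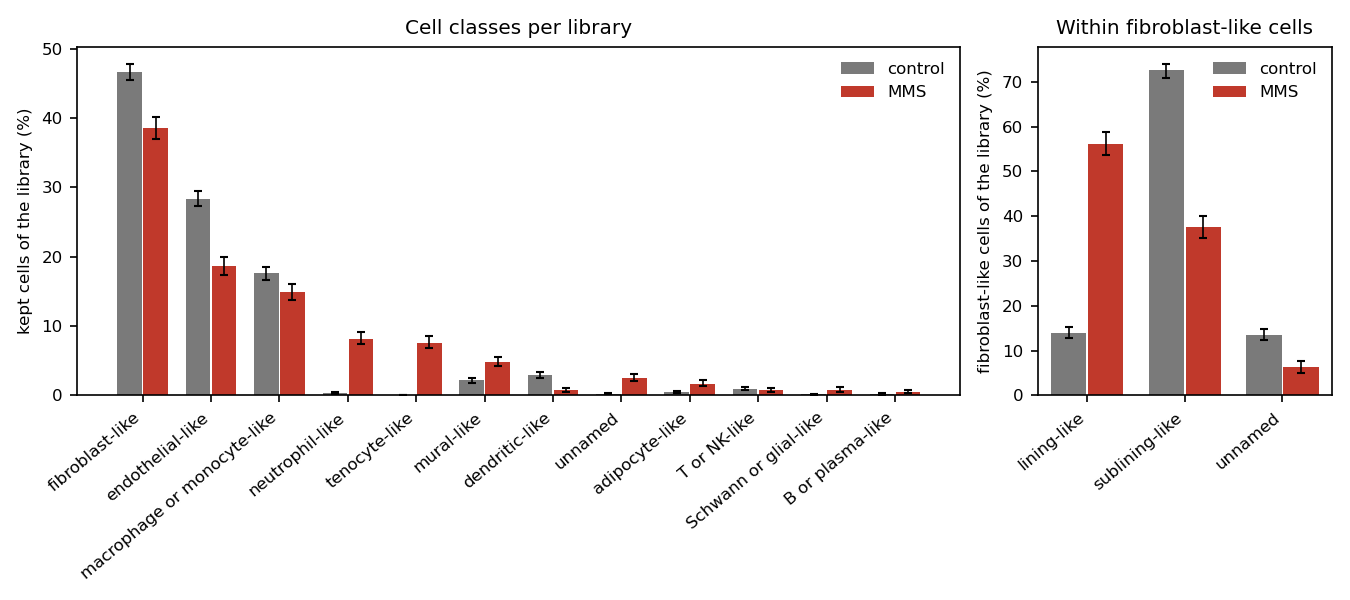
Percent of kept cells in each class (left) and percent of fibroblast-like cells that were lining-like, sublining-like or unnamed (right), in the control (grey) and MMS (red) library. Bars start at 0 and error bars are exact 95% binomial intervals for counting error; lining-like cells were 13.9% of control and 56.2% of MMS fibroblast-like cells.

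The fibroblast-like cells were then split by the lining, the layer that faces the joint space. Lining-like cells were 13.9% (12.7 to 15.2) of control and 56.2% (53.6 to 58.7) of MMS fibroblast-like cells, 448 of 3217 against 815 of 1451. Sublining-like cells were 72.6% (71.0 to 74.1) in control and 37.6% (35.1 to 40.1) in MMS, and 13.5% and 6.27% stayed unnamed. With sub-clusters made without the lining and sublining marker genes, but still named from them, the lining-like shares were 14.2% (13.02 to 15.5) and 62.4% (59.8 to 64.9). Under the other filters and clusterings the difference of 42.2 points ranged from 33.5 to 54.2. In the reported sub-clusters, most MMS lining-like cells lay in 13 and 8 (357 and 234 cells), which held 13 and 16 control cells. Most control ones lay in 10, 3 and 9 (144, 100 and 80 cells). The mean lining marker score was 3.5 in sub-cluster 13 and 0.81 in 8. It was 3.67, 0.26 and 4.35 in 10, 3 and 9. Each library's lining-like share therefore includes cells with a low lining score.

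The next question was which genes differed between the libraries over the summed fibroblast-like cells. Mmp13, a collagenase, stood at 6.98 counts per 1000000 UMIs of the class (CPM) in control and 305 in MMS, a log2 ratio of 5.45 (95% interval 5.29 to 5.61), and its control UMIs came from 3 of 3217 cells. Slpi, a secreted inhibitor of neutrophil elastase, stood at 11.7 and 282 CPM, log2 ratio 4.59 (4.47 to 4.72). Nt5dc2 stood at 7.19 and 268 CPM, log2 ratio 5.22 (5.07 to 5.38). At the other end, Sult1e1, the oestrogen sulfotransferase, stood at 36.1 CPM in control and 0.229 in MMS, log2 ratio -7.30 (-8.43 to -6.37), and the terminal complement component C7 at 77.9 and 3.56 CPM, log2 ratio -4.45 (-4.70 to -4.21).

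Megf6 had 5 control UMIs against 809 in MMS (0.104 and 20.6 CPM, log2 ratio 7.62, 6.39 to 9.25). Olfr810, annotated as an olfactory receptor gene, had 0 UMIs in control and 446 in MMS (11.3 CPM), at least 181-fold higher against a floor of 3 counts. Other genes higher in MMS were Lrrc34 (log2 ratio 5.09), Susd5 (4.95), the exchange factor Plekhg4 (4.81), the mitochondrial protein gene Chchd10 (4.72), the collagen Col24a1 (4.37) and the cadherin Cdh22 (4.27). Genes lower in MMS were Lgi1 (log2 ratio -5.31), the neuronal splicing factor Rbfox3 (-5.25), the protocadherin Pcdh20 (-5.47), Stmn4 (-5.07), the histamine receptor Hrh2 (-4.99), the kinase Stk32a (-4.82), the actin-severing protein gene Scin (-4.46), the transporter Slc47a1 (-4.30) and the methyltransferase Inmt (-4.29). Tmem52 had 254 UMIs in control and 2 in MMS. Some of the genes named here were among the top genes of clusters held mostly by 1 library. Examples were Sult1e1 in cluster 4 (369 control and 2 MMS cells) and C7 and Stmn4 in cluster 16 (553 and 10). Mmp13 and Megf6 were top genes of cluster 23 (18 and 403). Change within a cell type was not separated from this difference in cluster makeup. By GENCODE coordinates, Mmp13 lies on chromosome 9 at 7272514 to 7283331, Megf6 on chromosome 4 at 154170730 to 154275713, Olfr810 on chromosome 10 at 129787289 to 129794917 and Sult1e1 on chromosome 5 at 87575969 to 87591594.

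**Figure D2:**
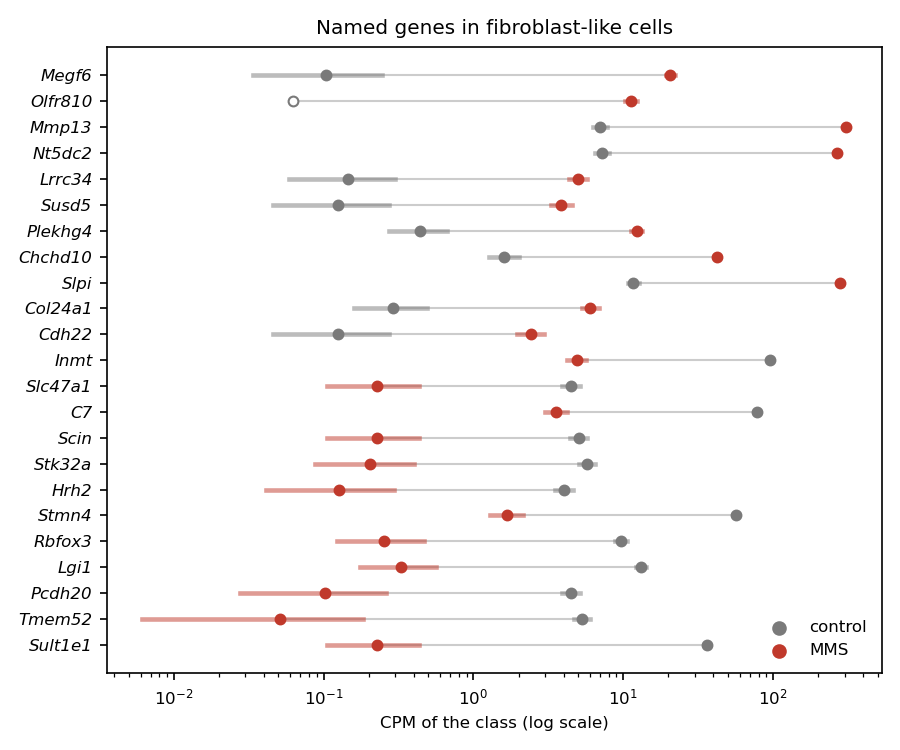
CPM (log axis) of named genes in fibroblast-like cells of the control (grey) and MMS (red) library, with exact 95% Poisson intervals as thick bars, sorted by the MMS to control ratio. The open circle marks Olfr810 in control, which had 0 UMIs and is drawn at 3 counts; Mmp13 runs from 6.98 to 305 CPM.

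Genes of activated and fibrotic fibroblasts were higher in MMS fibroblast-like cells for 19 of 22 members, with a median log2 ratio of 1.56, at percentile 100 of the matched random lists. The median was 0.84 within lining-like and 1.90 within sublining-like cells, and 0.997 between cells of the same depth, from 1.80 in the shallowest to 0.38 in the deepest bin, comparisons chosen after the result had been seen. The list was also higher in macrophage or monocyte-like (17 of 20, median 1.34), endothelial-like (15 of 19, median 0.93) and mural-like cells (20 of 22, median 1.19). Fibronectin (Fn1) stood at 7537 CPM in control and 21531 in MMS, the secreted phosphoprotein gene Spp1 at 27.5 and 511, the protease inhibitor Timp1 at 177 and 787, and Ccn2 at 600 and 1414. Tgfbi (466 and 333) and Aspn (607 and 451) were among the members that were lower. Matrix proteases were higher for 14 of 19 members (median 1.02, percentile 100), among them the collagen-degrading cathepsin Ctsk (317 and 901 CPM) and Mmp2 (657 and 1144), while Adamts1 was lower (174 and 85.8). Fibrillar and associated collagens were higher for 10 of 15 members (median 0.10, percentile 89.8): Col1a1 (8228 and 8784) and Col3a1 (12041 and 12909) lay close together, Col12a1 stood at 12.4 and 124 CPM, and Col1a2 (9354 and 6496) and Col15a1 (173 and 39.4) were lower. Within lining-like and within sublining-like cells alone, the collagen median was 0.57 and 0.78.

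All 9 lining markers were higher (median 1.32, percentile 100), led by Col22a1 (89.4 and 561 CPM), Htra4 (184 and 962) and the lubricin gene Prg4 (12593 and 59630). Prg4 was also seen in MMS macrophage or monocyte-like cells, at 213 CPM against 43.2 in control, a measure of free RNA. With lining-like and sublining-like cells weighted equally, the median of the lining list was -0.31, while it was 0.01 within lining-like cells (5 of 9 higher) and 1.28 within sublining-like cells (6 of 9 higher). Sublining and adventitial genes were lower for 8 of 9 members (median -0.99, percentile 0.01), including Dpp4 (66.2 and 6.92 CPM) and Cd34 (682 and 136). Most control fibroblast-like cells lay in clusters 3, 7, 16 and 4 (816, 667, 553 and 369 cells), and most MMS ones in clusters 9, 23 and 8 (541, 403 and 324 cells).

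Complement genes were lower in MMS fibroblast-like cells for 12 of 13 members (median -0.94, percentile 0), with C3 at 3131 and 918 CPM, C4b at 1999 and 646 and Serping1 at 2115 and 905. All 12 interferon response genes measured were lower (median -1.16, percentile 0.01), among them Ifi27l2a (308 and 24.6) and Usp18 (20.9 and 1.65). TGF-beta and BMP pathway genes were lower for 14 of 21 (median -0.87, percentile 0), with Tgfb2 at 173 and 71.4 CPM, although Tgfb1 stood at 41.2 and 103. Inflammatory cytokines and chemokines were lower for 12 of 21 (median -0.43, percentile 0.01), with Cxcl1 at 452 and 151, while Cxcl5 stood at 0.146 and 5.47. Ptgs2, the inducible cyclooxygenase, stood at 93.01 and 8.01 CPM. The neurotrophic and pain-linked list that also holds it was lower for 8 of 13 (median -0.60, percentile 0.25), against Sema3a at 39.4 and 118. Ptgs2 was a top gene of cluster 16 (553 control and 10 MMS cells), and C3 and C4b of cluster 3 (816 and 85). Change within a cell type was therefore not separated from cluster makeup for these genes either.

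Chondrogenic genes were higher for 10 of 15 (median 1.05, percentile 100), with the cartilage proteoglycan gene Acan at a log2 ratio of 4.26 and Sox5 at 83.4 and 206 CPM, while Comp stood at 2048 and 901. This list was also higher in macrophage or monocyte-like cells (8 of 8, median 1.504) and in mural-like cells (9 of 9, median 2.10). In endothelial-like cells its median was 0.24 (5 of 7 higher, percentile 73.5). Acan was among the top genes of the tenocyte-like cluster, so free RNA or admixed cells were not separated from the chondrogenic list. Wnt ligands and R-spondins were lower for 7 of 13 (median -0.49, percentile 0.36), spanning Wnt2 (8.19 and 0.585) and Rspo2 (46.7 and 130). Wnt inhibitors and targets were lower for 7 of 13 (median -0.04, percentile 27.2), spanning Frzb (7.87 and 0.610) and Ccn5 (177 and 715). Glycolysis and hypoxia genes were higher for 9 of 15 (median 0.30, percentile 99.1), with the glucose transporter Slc2a1 at 3.49 and 10.6 and Vegfa, the endothelial growth factor, at 107 and 36.5. Genes of dissociation and immediate early response were lower for 17 of 17 (median -1.27, percentile 0), with Fos at 4160 and 1426, Jun at 2476 and 715 and Atf3 at 719 and 139. The same list had medians of -0.13 in macrophage or monocyte-like and -0.28 in endothelial-like cells.

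Lists kept as checks were also read in fibroblast-like cells. Housekeeping genes had a median log2 ratio of 0.17 (9 of 14 higher, percentile 95.4), with Actb at 3434 and 3959 CPM. Sex-linked genes had a median of 0.01 (3 of 5 higher, percentile 48.9). Y-linked Ddx3y stood at 86.6 and 74.1 CPM, and Xist at 0.0418 and 0.280. Haemoglobin genes were higher for 5 of 5 (median 0.59, percentile 99.3), with Hbb-bs at 193 and 308, and skeletal muscle genes were lower for 6 of 7 (median -0.72, percentile 9.31), with Tnnt3 at 3.89 and 1.78.

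**Figure D3:**
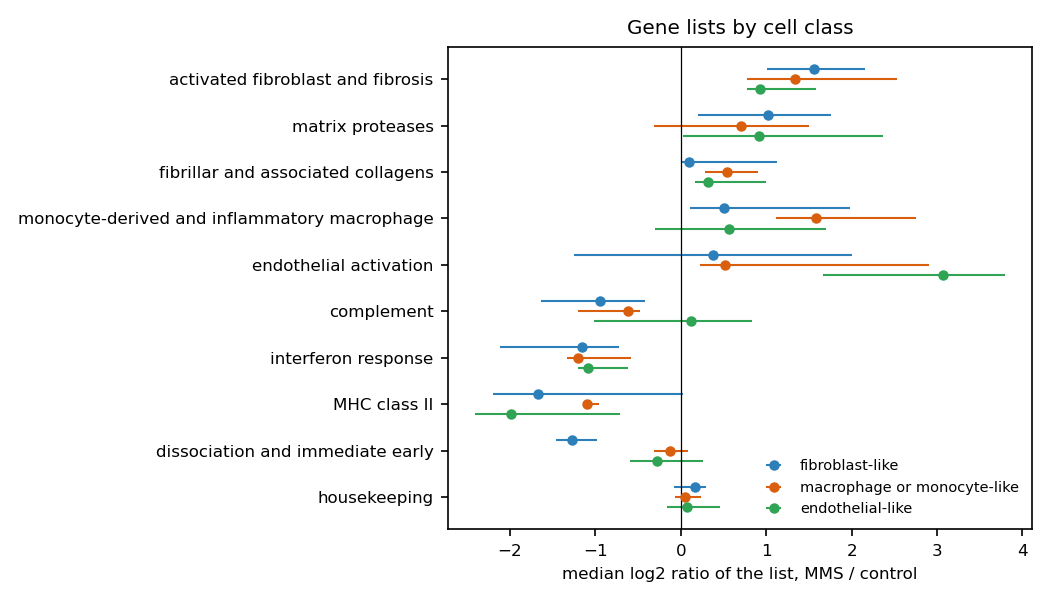
Median log2 ratio (MMS over control) of 10 gene lists in fibroblast-like (blue), macrophage or monocyte-like (orange) and endothelial-like (green) cells, with bars for the 95% range from resampling the members of each list. The interferon response list lies below 0 in each class, at -1.16, -1.20 and -1.08, and endothelial activation stands at 3.07 in endothelial-like cells; fibroblast lists in the other classes include free RNA.

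Macrophage or monocyte-like cells were compared in the same way. Retnla, a gene of alternatively activated macrophages, stood at 3660 CPM in control and 197 in MMS, log2 ratio -4.22 (-4.29 to -4.15). Acp5, the tartrate-resistant acid phosphatase of osteoclasts and some macrophages, stood at 5.23 and 90.8 CPM, log2 ratio 4.12 (3.79 to 4.46). Arg1, the arginase of alternatively activated macrophages, stood at 0.819 and 11.1, log2 ratio 3.76 (2.92 to 4.72), and the chemokine Ccl4 at 24.96 and 223, log2 ratio 3.16. Also higher in MMS were the cholesterol hydroxylase Ch25h (log2 ratio 3.53), Sirpb1c (3.50), the C-type lectins Clec4n (3.26) and Clec4d (3.22) and the chemokine receptor Ccr3 (3.25). Lower in MMS were Aldh1a2, which makes retinoic acid (log2 ratio -4.20), the calcium channel Ryr1 (-4.10), Upb1 (-3.69), Diras2 (-3.43), Hepacam2 (-2.79), the lectin Siglech (-2.73) and the homeobox gene Barx2 (-2.61). Retnla lies on chromosome 16 at 48842551 to 48844461 and Acp5 on chromosome 9 at 22126727 to 22135711.

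Monocyte-derived and inflammatory macrophage genes were higher for 14 of 15 members (median log2 ratio 1.58, percentile 100), with the neutrophil-attracting chemokine Cxcl2 at 1099 and 2380 CPM. That median was 0.74 with a mitochondrial limit of 5% and 0.66 with a minimum of 500 UMIs. The list was also higher in mural-like (8 of 8, median 1.44), endothelial-like (6 of 9, median 0.57) and fibroblast-like cells (11 of 15, median 0.51). Free RNA or admixed cells were not separated from it. Lipid-associated macrophage genes were higher for 11 of 12 (median 0.56, percentile 100), with Apoe at 4477 and 9068 and Spp1 at 4.22 and 155; Spp1 stood at 12.7 CPM in MMS endothelial-like cells, a measure of free RNA, and at 7870 in tenocyte-like cells. Resident macrophage genes were lower for 12 of 13 (median -0.23, percentile 0.62), with Lyve1 at 2062 and 1164, Vsig4 at 1513 and 1292 and Cx3cr1 higher at 233 and 333. Their median was -0.0547 with a mitochondrial limit of 20% and -0.0579 at cluster resolution 0.5. All 7 MHC class II genes were lower (median -1.10, percentile 0), with Cd74 at 5693 and 2646 and H2-Ab1 at 2126 and 966, and their median was -1.71 with a minimum of 500 UMIs.

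All 11 interferon response genes measured were lower in MMS macrophage or monocyte-like cells (median -1.20, percentile 0), with Ifi27l2a at 1857 and 1371 CPM. Complement genes were lower for 12 of 13 (median -0.61, percentile 0), with C1qa at 6598 and 4329, against C4b at 154 and 324. Inflammatory cytokines and chemokines were higher for 13 of 21 (median 0.55, percentile 100), with Ccl8 at 133 and 607 and Ccl7 at 214 and 398. Glycolysis and hypoxia genes were higher for 13 of 15 (median 0.70, percentile 100), with Pkm at 269 and 484. Haemoglobin genes were higher for 5 of 5 (median 3.36, percentile 100), with Hbb-bs at 138 and 1416, but their median was -1.41 at cluster resolution 2.0. At that resolution, an unnamed cluster of 81 cells scored highest as erythroid (5.74) and next as mast or basophil (5.69). Cluster 19 of the reported class had mast or basophil as its next class (score 2.77). Erythroid or mast-type cells were therefore not separated from the values of this class, those of its named genes included. Most macrophage or monocyte-like cells lay in clusters 13 and 15 in control (490 and 456 cells) and in clusters 13 and 19 in MMS (261 and 215 cells).

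**Figure D4:**
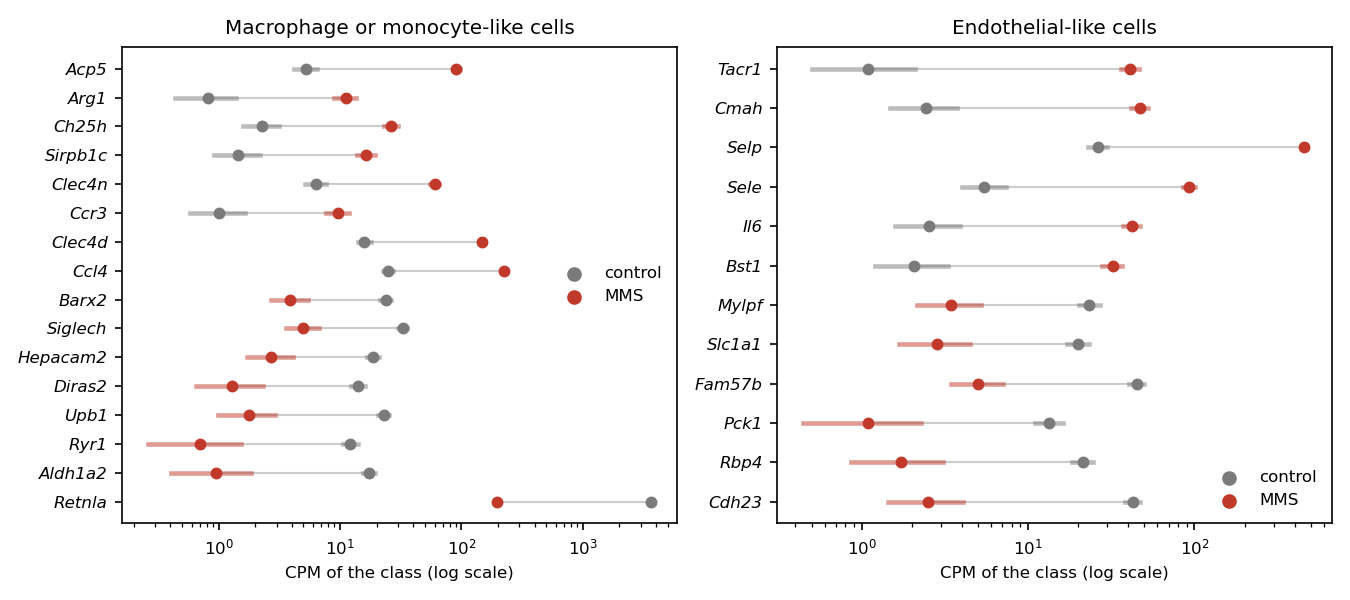
CPM (log axes) of the named genes in macrophage or monocyte-like cells (left) and endothelial-like cells (right) of the control (grey) and MMS (red) library, with exact 95% Poisson intervals as thick bars. Retnla runs from 3660 in control to 197 in MMS, and Selp from 26.2 to 457.

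Genes of endothelial-like cells with high ratios included selectins. P-selectin (Selp) stood at 26.2 CPM in control and 457 in MMS, log2 ratio 4.13 (3.92 to 4.33), and E-selectin (Sele) at 5.48 and 92.4, log2 ratio 4.08 (3.64 to 4.55). The substance P receptor gene Tacr1 stood at 1.10 and 41.0, log2 ratio 5.23 (4.28 to 6.37), and the cytokine Il6 at 2.56 and 42.0, log2 ratio 4.04 (3.40 to 4.75). Cmah (log2 ratio 4.27) and the ectoenzyme Bst1 (3.96) were also higher. Lower in MMS were the cadherin Cdh23 (-4.08), the retinol carrier Rbp4 (-3.62), the gluconeogenic enzyme Pck1 (-3.61), Fam57b (-3.16), the glutamate transporter Slc1a1 (-2.83) and the muscle myosin light chain Mylpf (-2.76). Selp and Sele were among the top 10 genes of endothelial-like cluster 6 (98 control and 245 MMS cells). Change within a cell type was not separated from this difference in makeup. Selp lies on chromosome 1 at 164115264 to 164150026.

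Endothelial activation genes were higher for 10 of 12 members (median log2 ratio 3.07, percentile 100), with Vwf at 50.6 and 404 CPM, Lrg1 at 79.8 and 725 and Il6st at 302 and 736. Cluster 6 held 98 of 1954 control and 245 of 703 MMS endothelial-like cells, while clusters 1 and 5 held most control cells (765 and 666). Vwf, Lrg1 and Plvap, like Selp and Sele, were among the top 10 genes of cluster 6. Their ratios were not separated from its larger share in MMS. With the clusters weighted equally, an alternative chosen after seeing the data, the median of the activation list was 0.95. Angiogenic and tip endothelial genes were higher for 13 of 17 (median 0.50, percentile 100), with Plvap at 328 and 1457 and Col4a1 at 1459 and 1936, whereas the VEGF receptor Kdr stood at 1330 and 849. All 12 interferon response genes measured were lower (median -1.08, percentile 0), with Ifi27l2a at 287 and 42.0 and Bst2 at 603 and 277. All 6 MHC class II genes measured were lower (median -1.98, percentile 0), with H2-Aa at 12.9 and 2.36. The macrophage genes C1qa and Retnla stood at 20.9 and 13.1 CPM in control endothelial-like cells and at 16.0 and 0 in MMS, so free RNA was not separated from these MHC class II values. Inflammatory cytokines and chemokines were higher for 11 of 15 (median 0.64, percentile 99.7), against Cxcl9 at 321 and 96.9. Haemoglobin genes were higher for 5 of 5 (median 1.24, percentile 99.9), and their median was -0.0727 with a minimum of 500 UMIs.

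Cell-cycle genes were compared last. At 2000 UMIs per cell, 1.76% (1.34 to 2.28) of control and 1.98% (1.31 to 2.87) of MMS fibroblast-like cells had at least 2 UMIs of the proliferation list, 56 of 3175 against 27 of 1361, with 42 and 90 shallower cells left out. The unthinned shares were 25.3% and 48.0%, at median depths of 13747 and 26798 UMIs. The shares were 4.45% and 5.31% in macrophage or monocyte-like cells and 7.06% and 6.55% in endothelial-like cells at 2000 UMIs. The cluster led by cell-cycle genes (17 control and 97 MMS cells) had stayed unnamed and was outside these classes, although it scored highest as fibroblast. Counted as fibroblast-like, an alternative added after the data were seen, it gave 2.22% (1.74 to 2.80) of control and 8.0% (6.66 to 9.52) of MMS cells, a difference of 5.78 points. The difference was 6.70 points with a mitochondrial limit of 20% and 5.43 at cluster resolution 2.0. In fibroblast-like cells the proliferation list was higher for 12 of 17 members (median 0.43, percentile 93.5). Summed over all kept cells, where the unnamed cycling cluster and other classes enter, it was higher for 18 of 18 (median 1.43, percentile 100), and chondrogenic genes for 16 of 17 (median 2.08, percentile 100).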

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

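The tests of filters, depth and precursor sums without Epor or Vpreb1 for neutrophil-like cells, of depth and lining-like cells for fibroblast-like cells, and of Tnmd in control cells for tenocyte-like cells were chosen after the results had been seen.

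Among barcodes the filters removed, which enter no comparison, 3.35% (2.51 to 4.39) of MMS barcodes had at least 1% of their UMIs from the neutrophil genes S100a8 and S100a9, 51 of 1521, against 0.0521% (0.00132 to 0.290) of control barcodes, 1 of 1919.

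Neutrophil-like cells made up more of the MMS library. The cell filters were argued against as a cause, since over all deposited barcodes the share with at least 1% S100a8 and S100a9 UMIs was 68.1 times as high in MMS, and depth was argued against by a ratio of 71.9 in kept cells thinned to 1000 UMIs. Precursor genes of neutrophils (Elane, Prtn3, Mpo and others) stood at 5.70 CPM in control and 345 in MMS, but erythroid precursor genes were 1.64 times as high in MMS (1.49 to 1.79), below the bound of 2 set for marrow cells, and B precursor genes 0.779 times (0.583 to 1.04). Epor held 511 of the 743 erythroid UMIs in control and Vpreb1 108 of the 112 B precursor UMIs, and without them the ratios were 4.34 (3.76 to 5.03) and 4.96 (1.66 to 19.95, 4 against 20 UMIs). Marrow cells in the sample may therefore account for the pattern or part of it, and entry of neutrophils into the MMS joint stays open as an untested hypothesis.

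Genes of the activated fibroblast list were higher in MMS fibroblast-like cells. Depth as the whole cause was argued against by a median log2 ratio of 0.997 between cells of the same depth. That is below the 1.56 over all fibroblast-like cells, so depth may account for part. The median ran from 1.80 in the shallowest to 0.38 in the deepest of 9 bins, not in steady steps. Depth is matched within a bin, so differences between bins do not show its effect. A larger lining-like part as the whole cause was argued against by medians of 0.84 within lining-like and 1.90 within sublining-like cells. Within each part, though, the libraries lay largely in different sub-clusters. Sublining-like 15 and 18 held 318 and 128 MMS cells against 19 and 1 of control. Makeup within each part was therefore not separated from the list. Free RNA was argued against by list members standing a median of 39.0 times higher in MMS fibroblast-like than in MMS endothelial-like cells. A response of fibroblasts in MMS mice may be the source, but with 1 library per group it cannot be separated from any other difference between the libraries.

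Tenocyte-like cells were found in the MMS library alone. Of removed control barcodes, 0.156% (3 of 1919) had UMIs of at least 3 tenocyte markers, against 1.51% (23 of 1521) in MMS. However, 1235 of the 1919 fell below the UMI minimum, where 3 markers can go undetected in any cell. The low share therefore cannot decide the question, and loss of tenocyte-like cells to the filters stays open. The highest correlation of these cells with a control fibroblast-like cluster, 0.828, was below the median of 0.865 between different control clusters and the lowest value of 0.879 within a cluster, as set beforehand for a type of its own, but a single type split between the libraries stays open, since the clustering that set the cells apart used the same genes, and no cluster took the name at resolution 0.5 or at mitochondrial limits of 20% and 5%. Tendon or ligament taken from MMS knees alone also stays open, since Tnmd in 12.4% (11.3 to 13.6) of control and 4.92% of MMS fibroblast-like cells at 2000 UMIs does not show tendon cells in control. A change in MMS mice may be the source too, and was not tested.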

How the results depend on the processing

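The alternatives that counted tenocyte-like cells as fibroblast-like, left out cluster 7 or the neutrophil-like and B or plasma-like cells, made sub-clusters without the markers, weighted clusters equally, left out cluster 11, counted the unnamed cluster as fibroblast-like or left Gm42418 and Malat1 out of totals were chosen after seeing the data. All 52 named gene and class pairs kept their direction in each of 788 alternative values. These pairs had been named for the most extreme ratios in the same libraries, so their kept direction is a weak check. Among alternative values of the main results, 267 stayed within the interval of the reported value, 56 moved outside it in the same direction and 3 turned sign from a reported value whose interval left out 0; for the other lists and classes the counts were 1091, 172 and 3. No scaling moved the median gene by over 0.1 in log2, apart from mural-like cells (0.11). The tenocyte-like and dendritic-like classes gave no value under settings in which no cluster took the name. Kept cells of such a class then lay in another class or in an unnamed cluster. At resolution 0.5, where no cluster took either name, the unnamed cluster held 104 cells. Some of these shifts therefore go with a change in which cells made up a class. How much of each shift that accounts for was not tested. Differences of shares are in points, MMS minus control.

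With a mitochondrial limit of 20%, the difference was -10.4 for fibroblast-like cells, -10.9 among non-haematopoietic cells, 35.3 for lining-like and 6.70 for cycling cells, and the resident macrophage and MHC class II medians were -0.0547 and -1.33. With a limit of 5%, it was 1.90 for mural-like, -7.90 for macrophage or monocyte-like, 11.1 for neutrophil-like, 37.3 for lining-like and 2.23 for cycling cells, and the monocyte-derived median was 0.74. With at least 500 UMIs, it was -12.4 for endothelial-like and 33.6 for lining-like and -0.105 for cycling cells (the interval of the reported value included 0), and the medians were 0.66 for monocyte-derived, -1.71 for MHC class II and -0.0727 (reversed) for haemoglobin in endothelial-like cells. With at least 2000 UMIs, it was -6.26 for endothelial-like, -5.60 for macrophage or monocyte-like, 6.04 for tenocyte-like, 54.2 for lining-like and 1.70 for cycling cells, with medians of -0.0551 (resident) and -1.23 (MHC class II). With doublets kept, it was -5.12 for macrophage or monocyte-like and 33.5 for lining-like cells, and the medians were -1.41 for MHC class II and -0.18 (reversed) for haemoglobin in endothelial-like cells.

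At cluster resolution 0.5, the difference was -0.131 for fibroblast-like, 2.26 (reversed) among non-haematopoietic, -4.95 for macrophage or monocyte-like and 36.0 for lining-like cells, with medians of -0.0579 (resident) and -1.23 (MHC class II). At resolution 2.0, it was -4.20 for fibroblast-like, -3.42 among non-haematopoietic, 6.003 for tenocyte-like, 47.6 for lining-like and 5.43 for cycling cells, and the haemoglobin median in macrophage or monocyte-like cells was -1.41 (reversed). With another seed, it was -5.65 for fibroblast-like, -5.20 among non-haematopoietic, -4.95 for macrophage or monocyte-like, 5.98 for tenocyte-like and 37.7 for lining-like cells, with medians of -0.0579 (resident) and -1.23 (MHC class II).

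Counting tenocyte-like cells as fibroblast-like gave -0.522 for fibroblast-like cells and 1.91 (reversed) among non-haematopoietic cells. Without cluster 7, the difference was -2.71 for fibroblast-like, -2.88 among non-haematopoietic, -12.6 for endothelial-like and -4.47 for macrophage or monocyte-like cells. Leaving out neutrophil-like and B or plasma-like cells gave -4.68 for fibroblast-like cells. Sub-clusters made without the markers, but still named from them, gave 48.2 for lining-like cells. For cycling cells, unthinned cells gave 22.7 and the unnamed cluster counted as fibroblast-like 5.78. The MHC class II median was -0.90 with every cell weighted the same, -0.95 with cells thinned to 2000 UMIs and -1.39 with clusters weighted equally. Weighting clusters equally gave 0.95 for endothelial activation, and weighting lining-like and sublining-like cells equally gave -0.31 (reversed) for the lining list, by construction without the difference in lining-like share. No paired analysis was possible because there was 1 library per group. Genes with few UMIs, such as Susd5 with 6 in control, are limited by depth.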

Other observations

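No test was run for the values given here, and the genes were chosen after their values were seen, apart from the lists.

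Mural-like cells numbered 151 in control and 183 in MMS. All 12 interferon response genes measured were lower in MMS mural-like cells (median log2 ratio -1.84, percentile 0), with Bst2 at 347 CPM in control and 101 in MMS and Isg15 at 124 and 33.9. Collagens were higher for 13 of 14 members (median 0.70, percentile 100), with Col3a1 at 1615 and 2629 and Col12a1 at 19.2 and 85.6. Lining fibroblast genes were higher too, for 9 of 9 (median 4.06), with Prg4 at 1127 and 22766 and Fn1 at 1077 and 9139, and fibroblast content of this class was not separated from its collagen values. Immediate early genes were lower for 16 of 17 (median -1.02, percentile 0). Over all genes with at least 50 UMIs in both libraries the median log2 ratio in this class was -0.11, and these values stand beside that shift.

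Neutrophil-like cells of the MMS library fell into nearly equal parts. Cluster 22 (153 cells) held the azurophil granule genes Elane at 1789, Prtn3 at 2448 and Mpo at 1259 CPM, with Retnlg at 1749. Cluster 26 (156 cells) held Retnlg at 30614 and the chemokine receptor Cxcr2 at 1097 CPM, with Elane at 0.595. In control, cluster 22 held 12 cells and cluster 26 held 8.

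Lining-like and sublining-like cells were also set apart for lists below 0 over all fibroblast-like cells. Interferon response genes were lower for 11 of 11 members in lining-like cells (median -1.72) and for 10 of 12 in sublining-like cells (median -0.83). Complement medians were -1.17 and -0.54, and immediate early medians -0.74 and -0.96.

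Olfr810 had UMIs in 7.37% of MMS fibroblast-like, 1.64% of mural-like and 0.348% of tenocyte-like cells and in none of the MMS macrophage or monocyte-like, endothelial-like and neutrophil-like cells, and in none of the control cells of these classes. Mmp13 had UMIs in 16.3% of MMS fibroblast-like cells at a median depth of 26798 UMIs, against 14.3% of MMS tenocyte-like cells (123 CPM), 4.37% of mural-like, 3.70% of T or NK-like, 3.55% of macrophage or monocyte-like, 2.59% of neutrophil-like and 1.56% of endothelial-like cells, which had other depths. In control, 0.0933% of fibroblast-like cells, 3 of 3217, held the 334 UMIs of that class. Control macrophage or monocyte-like cells had Mmp13 UMIs in 2.31% of cells, at 3.09 CPM against 2.48 in MMS. Control endothelial-like cells had them in 0.0512%, and control mural-like, neutrophil-like and T or NK-like cells in none.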
